A study of Mus musculus with 10 samples.

How the data were processed

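Per the labels, polyA RNA was taken from flash-frozen kidneys with a Qiagen RNeasy kit, 3 mice per pool, and stranded Illumina libraries were made from 1 ug of total RNA. The authors deposited 1 file per library with raw read counts per gene, in the layout that STAR writes, with counts for both strands together and for each strand. Their notes name STAR 2.5.1b and HTSeq, whose version is not given in the sources used here. The genome build named in the notes is UMD 3.1, a cattle assembly, while all 47729 gene identifiers in the deposited counts are mouse Ensembl identifiers; the mouse build and annotation release are not given in the sources used here, so no coordinates are printed. Symbols and chromosomes were looked up by identifier in GENCODE mouse M21, which matched 47310 identifiers.

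The strand column with the larger total was used; it held 13.8 to 18.4 times as many gene reads as the opposite strand. Libraries had 25.7 to 41.6 M reads (M for 1e6) in all, of which 70.8 to 76.1% were assigned to genes, 5.52 to 11.1% were unmapped, 8.93 to 10.8% mapped to several places, 6.69 to 10.4% lay outside annotated genes and 0.80 to 1.05% were ambiguous. The median library had 24.1 M gene reads. Between 19447 and 21786 genes had a read, the 10 most abundant genes held 13.3 to 18.9% of gene reads, and mitochondrially encoded genes 7.85 to 12.7%. Intervals on ratios of reads are exact binomial (Clopper-Pearson) at 95% and cover counting error only.

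Genes were kept by edgeR's filterByExpr with the 5 combinations of genotype and treatment as groups, a minimum count of 10 and a minimum total of 15, which left 16347 genes; 20654 genes had no read in any library. Counts were scaled by TMM (factors 0.904 to 1.08) and fitted with edgeR 4.0.16 in R 4.3.3 by a quasi-likelihood model with terms for sex, genotype and treatment, leaving 5 residual degrees of freedom. The replicates of a level of 1 factor are thus the libraries over the levels of the others. Interactions of treatment with sex and with R899X were each added to that model, leaving 4, and the contrasts within females and within males come from the fit with the sex interaction. The design, the tests, the 39 gene lists, the naming rule and the alternatives were fixed before the data were examined. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The SE of a log2 fold change is its size over the square root of the F statistic.

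Of 382 genes on the 39 lists, 361 were tested. Each list was tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the 39 lists of a comparison, and again with an estimated correlation and with fry. For each main effect the naming rule took up to 10 genes each way with the largest change among those past 0.05, with the same sign in every matched pair, a mean log2 level of at least 1 and an established name, and for interactions and contrasts within a sex up to 5 each way. It added up to 4 genes per list with the smallest p, the 5 smallest p where fewer than 5 genes passed, and Bmpr2, Xist, 4 Y-linked genes, Mt1, Mt2, Esr1, Kap, Ren1 and Havcr1 throughout. Genes named outside the rule are said to be so.

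The alternatives tried were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, no filter, a minimum count of 50, counts without regard to strand, a term for copper under each reading of the sample numbers, a model of 5 conditions and sex, fits to the libraries of the genotypes compared alone, and leaving out each library in turn. The fit was also tested on simulated data with 50 genes changed at each of 4 fold changes: at 2-fold it recovered 76% for sex, 74% for 16OHE, 68% for R899X, 62% for Delx4, 40% for 16OHE by sex and 34% for 16OHE by R899X. The counts of the opposite strand, unmapped reads and reads outside genes were used for quality values only. Sequence reads and measurements of copper in the animals are not part of the deposit used here and were not analysed here. Results for some single genes are not reported here.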

Results

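Messenger RNA from flash-frozen mouse kidney was sequenced in 10 libraries, each made from the pooled kidneys of 3 animals. Of these, 8 libraries crossed 2 genotypes, Rosa and R899X, with 2 treatments, control and 16OHE, in females and males, and the other 2 were Delx4 controls, 1 from each sex. R899X and Delx4 are mutation types of Bmpr2, which encodes the type II receptor for bone morphogenetic proteins, and Rosa was the comparison genotype. 16OHE is not spelled out in the labels; the abbreviation is commonly used for a hydroxylated estrone, an estrogen metabolite. The comparisons below address how sex, an estrogen and the Bmpr2 genotype were reflected in kidney transcripts. Each combination of genotype, treatment and sex had 1 library, so no spread between like pools could be measured. The p-values rest on how far libraries depart from the fitted terms, which mixes spread between pools with interactions not in the model. They do not measure the spread between animals.

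Reads assigned to genes, in units of 1e6 (M), numbered 19.2 M in the Rosa control female, 23.1 M in the Rosa control male, 24.1 M in each of the Rosa 16OHE female and the Rosa 16OHE male, 23.6 M in the R899X control female and 29.4 M in the R899X control male. They numbered 22.3 M in the R899X 16OHE female, 25.9 M in the R899X 16OHE male, 30.7 M in the Delx4 control female and 25.7 M in the Delx4 control male. The leading principal component held 36.6% of the variance and separated males from females. The next held 24.3% and separated 16OHE from control. The Rosa control female stood apart from the other 9 libraries on the component after those, at -42.1, which held 8.54% of the variance. Mitochondrially encoded genes held 7.85 to 8.98% of gene reads with 16OHE and 8.54 to 12.7% in controls. In the R899X control male and both 16OHE males the ratio of reads on the expected to the opposite strand was 13.8 to 14.2 and the gene with the most reads was Gm42418. In the other 7 libraries these were 15.8 to 18.4 and mt-Co1. Across genes, the 8 pairs of libraries of the same sex and treatment had Pearson correlations of 0.980 to 0.988, and the 37 other pairs 0.949 to 0.980. Levels are given as TMM-scaled CPM, mean ± SD, and changes as log2 fold changes ± SE.

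Genes with large differences between male and female kidneys included single genes of transporters, enzymes and a growth factor. The differences are averages over control and 16OHE libraries. The response to 16OHE differed between the sexes for 393 genes, described below, among them Inmt and Fabp1. For these the average is not the difference in untreated kidneys. Higher in males were Cyp2j13, a cytochrome P450, by 7.54 ± 0.81, with 342 ± 202 CPM in males and 1.77 ± 2.37 in females (n = 5 against 5). The organic anion transporter gene Slco1a1 was higher by 7.48 ± 0.45, the protease inhibitor gene Pzp by 7.12 ± 0.53 and the amino acid transporter gene Slc7a13 by 6.90 ± 0.72. Lower in males was Igf2, which encodes a growth factor, at -6.82 ± 0.35 with 2.60 ± 0.97 CPM against 349 ± 250.0 in females. Hdc, whose product makes histamine, was at -6.08 ± 0.49. Kap, the kidney androgen-regulated protein gene and the best known androgen target of the mouse kidney, rose by 2.03 ± 0.19 in males, from 4571 to 17939 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3150 of 16347 genes passed at 0.05. Of these, 1482 were higher in males and 1668 lower, and 651 changed more than 2-fold.

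Other genes far higher in males were the glucuronosyltransferase gene Ugt2b37 (6.55 ± 0.47) and the organic anion transporter genes Slc22a28 (4.81 ± 0.29) and Slc22a30 (4.27 ± 0.41). The methyltransferase gene Inmt (4.76 ± 0.83) and the fatty acid hydroxylase gene Cyp4a12a (4.70 ± 0.45) were higher too. Far lower in males were the glucuronosyltransferase genes Ugt1a2 (-5.86 ± 0.80) and Ugt2b34 (-3.32 ± 0.25), Slc17a2 of the phosphate transporter family (-4.08 ± 0.60) and the fatty acid hydroxylase gene Cyp4a14 (-3.98 ± 0.82). So were the efflux pump gene Abcc3 (-3.72 ± 0.55), the fatty acid binding protein gene Fabp1 (-3.55 ± 0.67) and Bhmt, which encodes betaine-homocysteine methyltransferase (-3.52 ± 0.30). Each of these had the same sign in all 5 matched pairs, with adjusted p from 9.98e-06 for Slc22a28 to 0.00866 for Cyp4a14. Xist, transcribed from the inactive X, fell by 8.73, and the Y-linked genes Eif2s3y and Ddx3y were higher by 9.39 ± 0.14 and 8.46 ± 0.14. The estrogen receptor gene Esr1 was higher in males by 1.26 ± 0.19. The difference for Bmpr2, 0.59 ± 0.27, did not pass (adjusted p = 0.164). Ren1, the renin gene, was lower in males, at -0.71 ± 0.14. The metallothionein genes Mt1 and Mt2, which bind copper and zinc, were at -0.85 ± 0.12 and -0.88 ± 0.07.

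Of 15 male-biased kidney genes fixed as a list, 13 were higher in males and none lower, with 15 higher when adjusted over the list alone (camera, adjusted p = 3.81e-25; adjusted p = 0.116 with an estimated correlation). Of 10 female-biased genes, 4 were lower and 1 higher, with 7 and 2 adjusted over the list alone (camera, adjusted p = 0.0250; adjusted p = 0.444 with an estimated correlation). The higher gene was Akr1c14, a steroid-reducing enzyme gene, by 3.45 ± 0.30. All 4 Y-linked genes were higher (camera, adjusted p = 4.11e-189; adjusted p = 0.000537 with an estimated correlation). No other list call held with an estimated correlation in any comparison. All 5 X genes that escape inactivation were lower (camera, adjusted p = 7.03e-15; adjusted p = 0.0796 with an estimated correlation). For these lists, the counts adjusted over the list alone were the same, at 4 and 5.

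All 7 podocyte markers fell in males (7 adjusted over the list alone; camera, adjusted p = 4.09e-14; adjusted p = 0.116 with an estimated correlation). They included the slit diaphragm gene Nphs1 (-1.05 ± 0.10), the surface mucin gene Podxl (-0.78 ± 0.06) and the cytoskeletal gene Synpo (-0.69 ± 0.07). Of 9 endothelial markers 8 fell, with 8 adjusted over the list alone (camera, adjusted p = 5.50e-07; adjusted p = 0.116 with an estimated correlation). The receptor genes Tek and Kdr were at -0.54 ± 0.07 and -0.52 ± 0.08. All 7 intercalated cell markers fell, with 7 adjusted over the list alone (camera, adjusted p = 3.92e-06; adjusted p = 0.116 with an estimated correlation). The proton pump gene Atp6v0d2 was at -0.61 ± 0.06 and the anion exchanger gene Slc26a4 at -0.57 ± 0.11. All 6 distal convoluted tubule markers fell, with 6 adjusted over the list alone (camera, adjusted p = 3.13e-05; adjusted p = 0.208 with an estimated correlation). Slc12a3, the thiazide-sensitive salt transporter gene, was at -0.57 ± 0.10. In the renin-angiotensin and salt transport list, 5 of 10 genes fell and 1 rose, with 5 and 1 adjusted over the list alone (camera, adjusted p = 0.0287; adjusted p = 0.268 with an estimated correlation). The salt-retention kinase gene Sgk1 was at -1.24 ± 0.10.

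In the gluconeogenesis and insulin response list, 5 of 10 genes fell in males, with 7 adjusted over the list alone (camera, adjusted p = 0.00233; adjusted p = 0.116 with an estimated correlation). The glucose-6-phosphatase gene G6pc was at -0.89 ± 0.12 and Pck1 at -0.62 ± 0.13. In the list of PPARA targets and fatty acid oxidation, 5 of 12 genes fell and 1 rose, with 6 and 1 adjusted over the list alone (camera, adjusted p = 0.0173; adjusted p = 0.557 with an estimated correlation). Acaa2, which encodes a thiolase, was at -1.46 ± 0.17. Of 7 B cell and plasma cell genes 2 rose, with 3 adjusted over the list alone (camera, adjusted p = 0.00323; adjusted p = 0.201 with an estimated correlation). They were the immunoglobulin genes Igkc (2.53 ± 0.35) and Jchain (2.30 ± 0.34). In the skeletal muscle list 1 of 2 measured genes was lower, with 1 adjusted over the list alone (camera, adjusted p = 0.0369; adjusted p = 0.208 with an estimated correlation). This was the myosin gene Myh1, with 39 reads over the male libraries and 908 over the female ones. Camera did not call the proximal tubule list, where 1 of 12 genes rose and 3 fell. The gene that rose was the organic anion transporter gene Slc22a6, by 1.30 ± 0.13. Nor did it call the thick ascending limb, where 4 of 6 fell, the collecting duct principal cell, where 3 of 8 fell, or the macrophage and myeloid list, where 2 of 9 fell. In steroid and xenobiotic metabolism, likewise not called, 5 of 13 rose and 3 fell. The count of 3150 genes was 1950 without the Delx4 control female, 1964 without the Delx4 control male, 1989 without the R899X control female and 2039 without the Rosa control male. It was 2034 with a term for copper supplementation as assigned by library number, which is described with the treatment below.

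Genes that rose in kidneys of mice given 16OHE included those of a growth factor, a water channel, a collagen and a hormone receptor. Tgfb2, a transforming growth factor beta gene, rose by 4.86 ± 0.54, from 3.76 ± 1.12 to 129 ± 98.4 CPM (n = 4 against 4). The water channel gene Aqp8 rose by 4.69 ± 0.43 and the collagen VI gene Col6a1 by 2.84 ± 0.16. The progesterone receptor gene Pgr, a standard estrogen target, rose by 2.44 ± 0.22. The chemokine gene Cxcl1 fell by 2.20, the prostaglandin synthase gene Ptgs2 by 1.95 and the heme oxygenase gene Hmox1 by 1.07. By edgeR's quasi-likelihood test, 947 genes passed, 597 higher and 350 lower with 16OHE, and 358 changed more than 2-fold.

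Other genes with large increases were Ano5 of the anoctamin family (4.86 ± 0.44), the arylsulfatase gene Arsi (4.03 ± 0.53), Il18bp, whose product binds and blocks interleukin 18 (3.65 ± 0.49), and Hdc (3.43 ± 0.54). Tgfb3 (3.35 ± 0.53), the neurotrophin receptor gene Ngfr (3.32 ± 0.23), the spindle component gene Haus4 (3.31 ± 0.24) and Cyp27b1, whose product activates vitamin D (3.18 ± 0.54), rose as well. Large decreases were measured for Cyp4a12a (-2.04 ± 0.48), the glucuronosyltransferase genes Ugt1a10 (-1.81 ± 0.19) and Ugt1a9 (-1.59 ± 0.18) and the aldehyde dehydrogenase gene Aldh1a7 (-1.74 ± 0.20). Others were measured for Depp1 (-1.64 ± 0.34), the mitochondrial carrier gene Slc25a25 (-1.56 ± 0.19), Extl1 (-1.55 ± 0.32) and the histidine catabolism gene Ftcd (-1.54 ± 0.21). All had the same sign in the 4 matched pairs, with adjusted p from 8.27e-05 for Ngfr to 0.0369 for Cyp4a12a. Chosen after their values were seen, 3 further genes were near the limit of detection in every control library and plainly present with 16OHE. Dhrs9, a retinol dehydrogenase gene (ENSMUSG00000027068), had at most 0.29 CPM in controls and 23.5 to 69.2 with 16OHE. The collagen VI gene Col6a4 (ENSMUSG00000032572) had at most 0.28 and 17.5 to 40.8, and the mast cell tryptase gene Tpsab1 (ENSMUSG00000024173) at most 0.24 and 10.3 to 14.9.

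**Figure D1:**
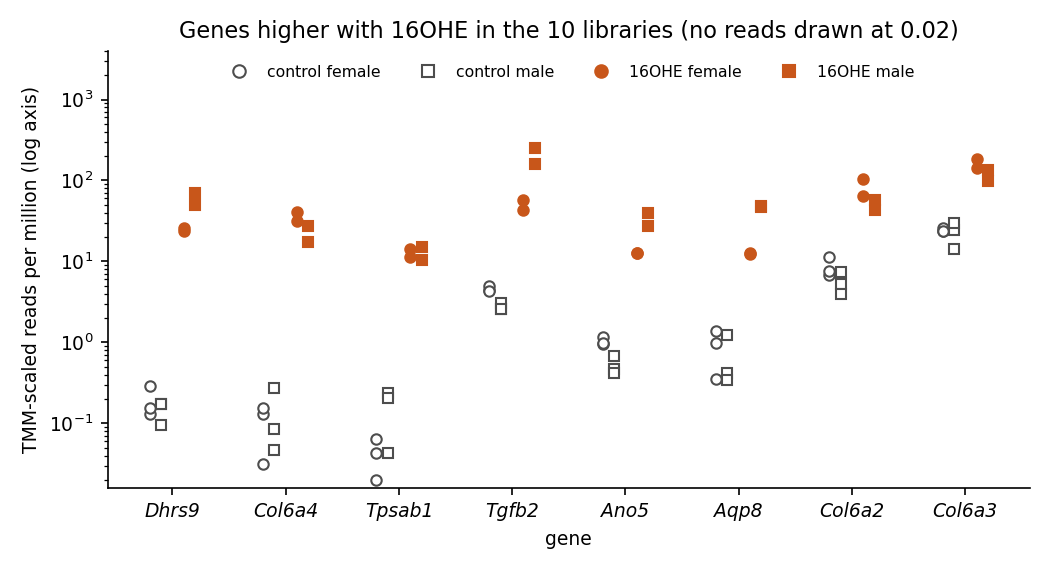
Levels of 8 genes in the 10 libraries, in TMM-scaled CPM on a log axis. Open symbols are controls, filled symbols 16OHE, circles females and squares males, 1 library each, and each of the 4 16OHE libraries lies above each of the 6 controls for every gene shown, with Dhrs9 at 23.5 to 69.2 against at most 0.29.

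In the extracellular matrix and fibrosis list, 8 of 11 genes rose with 16OHE and none fell, with 8 adjusted over the list alone (camera, adjusted p = 3.58e-17; adjusted p = 0.401 with an estimated correlation). They included the fibronectin gene Fn1 (1.65 ± 0.13) and the collagen I gene Col1a1 (1.74 ± 0.28). Over 35 measured collagen genes, a set assembled after the values were seen, 16 rose and 1 fell, Col27a1 by 1.11. Of 6 collagen VI genes 4 rose, Col6a1, Col6a2 (3.06 ± 0.20), Col6a3 (2.65 ± 0.21) and Col6a4. Of 9 mural and fibroblast markers 4 rose, with 4 adjusted over the list alone (camera, adjusted p = 0.0223; adjusted p = 0.782 with an estimated correlation). Among them were Col3a1 (1.59 ± 0.32), the proteoglycan gene Dcn (1.31 ± 0.27) and the pericyte receptor gene Pdgfrb (0.91 ± 0.13). Of 13 estrogen-responsive genes 5 rose and none fell, with 6 and 1 adjusted over the list alone (camera, adjusted p = 0.00251; adjusted p = 0.401 with an estimated correlation). Beside Pgr they included Igf1 (0.96 ± 0.19), Inhbb (0.66 ± 0.14) and Greb1 (0.53 ± 0.11).

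Of 9 mitochondrially encoded genes 1 fell, mt-Nd2 by 0.84, with 5 adjusted over the list alone (camera, adjusted p = 0.00172; adjusted p = 0.782 with an estimated correlation). Of 10 NRF2 targets 1 fell, the thioredoxin reductase gene Txnrd1 by 0.45, with 7 adjusted over the list alone (camera, adjusted p = 0.0143; adjusted p = 0.782 with an estimated correlation). Of 10 gluconeogenesis and insulin response genes 3 fell, with 3 adjusted over the list alone (camera, adjusted p = 0.0157; adjusted p = 0.401 with an estimated correlation). They were the glucose transporter gene Slc2a2 (-0.63 ± 0.11), the insulin receptor substrate gene Irs2 (-0.56 ± 0.07) and G6pc (-0.55 ± 0.13). Of 9 ER stress genes 2 fell, Trib3 (-2.07 ± 0.41) and Herpud1 (-0.44 ± 0.08), with 4 adjusted over the list alone (camera, adjusted p = 0.0223; adjusted p = 0.782 with an estimated correlation). Of 10 immediate early genes 1 fell, the phosphatase gene Dusp1 by 1.27, with 3 adjusted over the list alone (camera, adjusted p = 0.0274; adjusted p = 0.782 with an estimated correlation). Of 7 B cell and plasma cell genes 2 rose, with 2 adjusted over the list alone (camera, adjusted p = 0.0485; adjusted p = 0.782 with an estimated correlation). These were Jchain (2.49 ± 0.38) and Igkc (2.30 ± 0.39). No cell cycle gene passed, over all genes or adjusted over the list alone. Camera called the list of 9 higher (adjusted p = 0.0321; adjusted p = 0.782 with an estimated correlation).

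Male-biased genes had 1 of 15 higher and 1 lower with 16OHE, with 1 and 7 adjusted over the list alone (camera, adjusted p = 0.0186; adjusted p = 0.782 with an estimated correlation). Female-biased genes had 2 of 10 higher, with 5 adjusted over the list alone (camera, adjusted p = 0.0301; adjusted p = 0.782 with an estimated correlation). Among lists without a camera call, the iron handling list had 1 of 9 higher, the iron exporter gene Slc40a1 (0.67 ± 0.12). It had 3 lower, Hmox1, the transferrin receptor gene Tfrc (-0.61 ± 0.12) and the ferritin gene Fth1 (-0.52 ± 0.11). The copper handling list had 2 of 16 higher, the ceruloplasmin gene Cp (0.75 ± 0.16) and Mt2 (0.41 ± 0.08). The proximal tubule list had 1 of 12 higher, the megalin gene Lrp2 (0.42 ± 0.09), and 2 lower, among them the dicarboxylate transporter gene Slc13a3 (-1.06 ± 0.17). Cholesterol synthesis had 2 of 11 higher, among them the squalene epoxidase gene Sqle (0.77 ± 0.09), and 1 lower, Insig1 (-0.63 ± 0.11). The circadian clock had Cry1 higher (0.82 ± 0.20) and Ciart lower (-1.32 ± 0.16) of 14. Steroid and xenobiotic metabolism had 2 of 13 higher, among them the estrogen hydroxylase gene Cyp1b1 (0.69 ± 0.09), and 1 lower, Hsd17b4 (-0.36 ± 0.09). Of 18 genes for BMP receptors, ligands and SMADs 1 fell, the ligand gene Bmp7 by 0.48, and none of 11 BMP target genes passed. The interferon response list had Bst2 higher (0.75 ± 0.14) of 11 and tubular injury had Vcam1 higher (0.63 ± 0.14) of 10. PPARA targets had Plin2 lower (-0.39 ± 0.07) of 12 and the principal cell list had the water channel gene Aqp3 lower (-0.52 ± 0.10) of 8. No member passed in the podocyte, endothelial, intercalated cell, distal convoluted tubule, thick ascending limb, macrophage and myeloid or T cell lists. None passed in the adipocyte, erythroid, adrenal cortex, skeletal muscle, renin-angiotensin and salt transport, nuclear oxidative phosphorylation, Y-linked or X escape lists.

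The series text states that 5 numbered samples came from animals given minerals to raise copper, without saying how the samples are numbered. If the numbers are those of the sequencing libraries, the supplemented ones were all 4 16OHE libraries and 1 of 6 controls, the R899X control female. With a term for copper so assigned, 13 genes passed for 16OHE. If they are positions in the sample list, 3 16OHE libraries and 2 controls were supplemented and 938 passed, of which 709 were among the 947. The count of 947 was 396 without the Rosa 16OHE male, 453 without the Rosa control male, 471 without the R899X 16OHE male, 521 without the Rosa control female, 536 without the R899X control male and 596 without the R899X control female. DESeq2 called 1505.

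The response to 16OHE differed between the sexes for some genes that themselves differ between male and female kidneys. Slc7a12, an amino acid transporter gene of the female-biased list, rose in males from 9.56 to 518 CPM (n = 2 against 2) and was at 0.32 ± 0.33 in females. The difference between the responses was 5.68 ± 0.48. Cyp7b1, an oxysterol and steroid hydroxylase gene of the male-biased list, rose by 5.09 ± 0.38 in females and fell by 1.04 in males, a difference of -6.14 ± 0.47. By the interaction term, 393 genes passed, 219 with the higher and 174 with the lower response in males. Of these, 185 had fitted changes of opposite sign in the sexes, of which 6 passed in each sex, 198 had the same sign and a larger size in males, and 10 had the same sign and a larger size in females.

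The response was higher in males than in females for Nptx1 (4.74 ± 0.59), Slc17a2 (4.21 ± 0.56), Fabp1 (4.07 ± 0.52) and Ugt1a2 (4.05 ± 0.32). It was also higher for the prolactin receptor gene Prlr (3.87 ± 0.49) and the cytokine signalling inhibitor gene Socs2 (2.15 ± 0.20). It was lower in males for Inmt (-4.44 ± 0.39), Itih2 (-4.44 ± 0.40), Rtp3 (-4.39 ± 0.61), Cyp2j13 (-4.30 ± 0.76), the polyamine synthesis gene Odc1 (-2.09 ± 0.26) and the cyclin gene Ccnd1 (-1.46 ± 0.18). The adjusted p of these 12 genes ranged from 0.000281 for Ugt1a2 to 0.0137 for Cyp2j13. Of 15 male-biased genes, 7 had a lower response in males and none a higher, with 12 adjusted over the list alone (camera, adjusted p = 9.69e-30; adjusted p = 0.238 with an estimated correlation). Of 10 female-biased genes, 7 had a higher response and 1 a lower, Cyp2a4, with 8 and 2 adjusted over the list alone (camera, adjusted p = 1.61e-15; adjusted p = 0.161 with an estimated correlation). Not all of that list was higher in females here. Over all libraries, males over females, Akr1c14 was at 3.45, Cyp2a4 at 0.86 and Hao2 at 0.12, of which only Akr1c14 passed. Of 12 PPARA target and fatty acid oxidation genes 4 had a higher response in males, with 8 adjusted over the list alone (camera, adjusted p = 2.74e-13; adjusted p = 0.318 with an estimated correlation).

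Of 10 renin-angiotensin and salt transport genes 2 had a higher response in males, with 2 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.00714; adjusted p = 0.322 with an estimated correlation). They were the angiotensinogen gene Agt (1.76 ± 0.18) and Ren1 (0.76 ± 0.16). Of 12 proximal tubule genes 2 had a lower response in males, with 4 adjusted over the list alone (camera, adjusted p = 0.00327; adjusted p = 0.320 with an estimated correlation). They were the phosphate transporter gene Slc34a1 (-0.99 ± 0.16) and Slc13a3 (-0.80 ± 0.17). Camera also called the distal convoluted tubule list higher, with 1 of 6 genes, the magnesium channel gene Trpm6 (0.69 ± 0.14), and 2 adjusted over the list alone (adjusted p = 0.0118; adjusted p = 0.322 with an estimated correlation). The thick ascending limb list was called higher, with none of 6 and 4 adjusted over the list alone (adjusted p = 0.000908; adjusted p = 0.320 with an estimated correlation). It called the mural and fibroblast list lower, with 1 of 9 genes, Tagln (-0.80 ± 0.15), and 4 adjusted over the list alone (adjusted p = 0.00163; adjusted p = 0.802 with an estimated correlation). The immediate early list was called lower, with none of 10 and 5 adjusted over the list alone (adjusted p = 0.000383; adjusted p = 0.802 with an estimated correlation). The count of 393 genes was 113 without the Rosa 16OHE female, 138 without the Rosa 16OHE male, 139 without the R899X 16OHE female, 235 without the Delx4 control female, 245 without the Delx4 control male and 246 without the R899X 16OHE male. With no filter on low counts it was 981, 477 with the higher and 504 with the lower response in males.

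**Figure D2:**
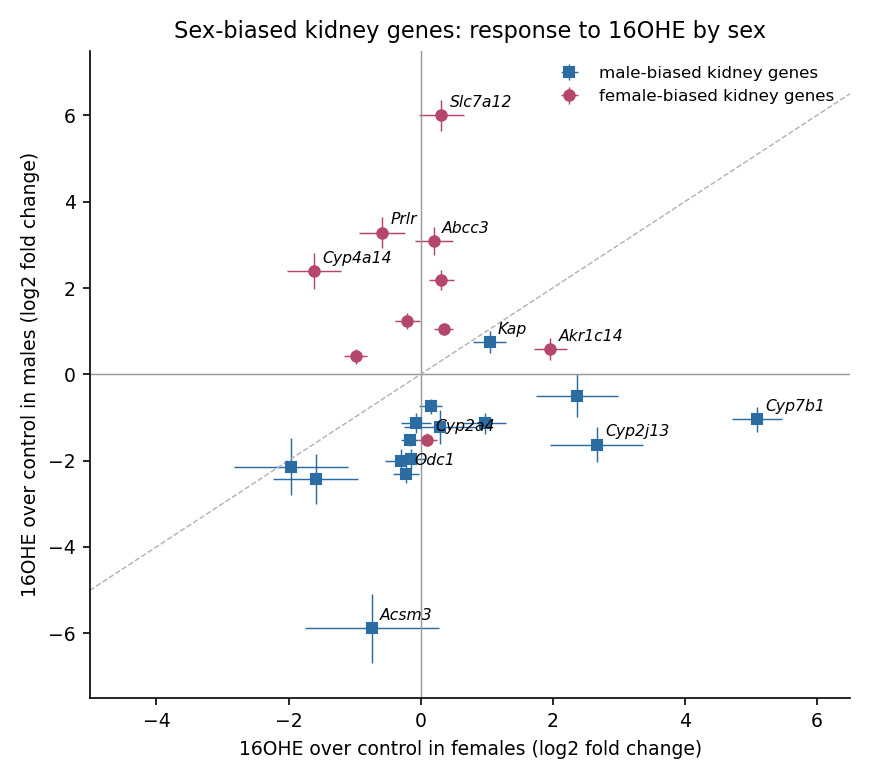
Change with 16OHE in females (horizontal) and in males (vertical) for the 15 male-biased (squares) and 10 female-biased (circles) kidney genes, as log2 fold changes with SE bars from 2 libraries against 2 in each sex. The dashed line marks equal change, male-biased genes lie mostly below 0 in males, with a median of -1.52, and female-biased genes mostly above it, with a median of 1.71. Colors follow the lists as fixed, but Akr1c14 and Cyp2a4 of the female-biased list were higher in males over all libraries, at 3.45 and 0.86.

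Within males, 16OHE raised the angiotensinogen gene Agt by 1.81 ± 0.13, Abcc3 by 3.09 ± 0.33, Prlr by 3.28 ± 0.37 and Socs2 by 2.82 ± 0.15. It also raised Tgfb2 by 6.18 ± 0.13, Ano5 by 6.04 ± 0.24, Aqp8 by 5.71 ± 0.27 and Arsi by 5.31 ± 0.35 (n = 2 against 2 for each). Acsm3, which encodes a medium-chain acyl-CoA synthetase, fell by 5.89, from 431 to 9.37 CPM. Rtp3 (-3.98 ± 0.47), Inmt (-3.54 ± 0.27), Pzp (-3.48 ± 0.38) and the immunoglobulin receptor gene Fcamr (-3.12 ± 0.29) fell too. So did Odc1 (-2.31 ± 0.21), the hydrolase gene Nudt19 (-1.96 ± 0.22) and Esr1 (-1.02 ± 0.18). The male-biased list had 11 of 15 genes lower and none higher, with 13 and 1 adjusted over the list alone (camera, adjusted p = 7.27e-13; adjusted p = 0.599 with an estimated correlation). The female-biased list had 7 of 10 higher and 1 lower, with 9 and 1 adjusted over the list alone (camera, adjusted p = 4.89e-11; adjusted p = 0.447 with an estimated correlation). The lower gene was Cyp2a4 (-1.52 ± 0.15), which was not higher in females in these libraries. Of 12 proximal tubule genes 1 rose and 5 fell, with 2 and 6 adjusted over the list alone (camera, adjusted p = 0.00306; adjusted p = 0.599 with an estimated correlation), among them Slc13a3 (-1.48 ± 0.13) and Slc34a1 (-1.03 ± 0.12). Kap, also of the male-biased list, was at 0.75 ± 0.25 in males (adjusted p = 0.0798) and 1.04 ± 0.25 in females (adjusted p = 0.0635). It passed for 16OHE over both sexes, at 0.90 ± 0.20 (adjusted p = 0.0322). The injury marker gene Havcr1 rose by 1.31 ± 0.37 (adjusted p = 0.0404). In all, 1933 genes passed, 1017 higher and 916 lower. The count was 679 without the Rosa 16OHE male, 1115 without the R899X 16OHE male and 1252 without the Rosa control male. With copper assigned by library number, both male 16OHE libraries and no male control were supplemented, and 428 genes passed with that term. These are not genes shown to respond apart from copper. Males alone cannot tell the treatments apart under this reading, and the term rests on the R899X control female.

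Within females, 16OHE raised Cyp7b1, Ano5 by 3.70 ± 0.23, the chemokine gene Ccl28 by 3.44 ± 0.32, Aqp8 by 3.44 ± 0.27, Hdc by 3.44 ± 0.54 and Pgr by 2.29 ± 0.29 (n = 2 against 2 for each). Fabp1 (-3.66 ± 0.32), Depp1 (-2.47 ± 0.22), Ugt1a10 (-1.91 ± 0.24), Igf2 (-1.79 ± 0.24) and the fatty acid hydroxylase gene Cyp4a10 (-1.44 ± 0.19) fell. Of 12 PPARA target and fatty acid oxidation genes 5 fell, with 7 lower and 1 higher adjusted over the list alone (camera, adjusted p = 7.58e-12; adjusted p = 0.386 with an estimated correlation). Of 11 extracellular matrix genes 6 rose, with 10 adjusted over the list alone (camera, adjusted p = 7.44e-23; adjusted p = 0.363 with an estimated correlation). Of the male-biased list 1 gene rose, Cyp7b1, with 5 adjusted over the list alone (camera, adjusted p = 0.0232; adjusted p = 0.708 with an estimated correlation). Its median change of -0.07 lay below 0 while its mean of 0.49 and the test pointed up. In all, 383 genes passed, 266 higher and 117 lower. The count was 103 without the Rosa 16OHE female, 127 without the R899X 16OHE female and 169 without the Rosa control female, and 83 with the copper term by library number. In both sexes 274 genes were called, against 45.3 if the calls were independent. Of them 207 were higher in both, against 16.5, and 61 lower in both, against 6.56. Both contrasts come from 1 fit, whose sex and genotype terms draw on controls of both sexes and on the Delx4 pair. In 10 simulated data sets with a response in males alone, and in 10 with a response in females alone, no gene was called in both sexes. On average 3406 genes were called in males and 0.1 in females in the former, and 1604 in females and 0 in males in the latter. These data sets thus tell only that a response in 1 sex did not carry over to the other through the shared fit. Of the 274 genes 6 had opposite directions: Cyp7b1, Itih2, Chst7 and Ankrd29 were higher in females and lower in males, and Cyp4a10 and Afm the reverse.

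R899X kidneys held more Bmpr2 transcript than Rosa kidneys in each of the 4 matched pairs, although the gene did not pass after adjustment. Bmpr2 (ENSMUSG00000067336) was at 502 ± 304 CPM in R899X and 104 ± 9.18 in Rosa (n = 4 against 4), a log2 difference of 2.09 ± 0.31 (adjusted p = 0.0728). By library it was 223 and 300.5 in the R899X control and 16OHE females and 596 and 888 in the R899X control and 16OHE males, against 93.4 to 115 in the 4 Rosa libraries. The splicing factor gene Cwc22 passed (2.01 ± 0.23, adjusted p = 0.0215), with 59.0 ± 22.1 CPM against 14.5 ± 1.57. So did the ganglioside synthesis gene B4galnt1 (1.51 ± 0.20, adjusted p = 0.0487), the translation initiation factor gene Eif3j2 (-1.16 ± 0.13, adjusted p = 0.0215) and the recombination cofactor gene Psmc3ip (-0.87 ± 0.11, adjusted p = 0.0333).

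By edgeR's quasi-likelihood test, 6 genes passed for R899X, 3 higher and 3 lower, against 34 by DESeq2 and 2 by limma-voom. The other 2 fell outside the naming rule and were chosen after their values were seen: the unnamed gene model Gm1821 (-0.86 ± 0.10), and Azgp1, which encodes a secreted zinc-binding glycoprotein. Azgp1 had 815 reads over the 4 R899X libraries, of which 607 were in the control male, and 4 over the 4 Rosa libraries, a ratio of 184 with a 95% counting interval of 71.6 to 677. Camera called 6 lists, of which none held with an estimated correlation and none had a member past the test over all genes. Higher were podocyte (2 of 7 higher adjusted over the list alone; camera, adjusted p = 0.00523; adjusted p = 0.689 with an estimated correlation), erythroid (none of 4; 0.00523 and 0.689) and immediate early (none of 10; 0.0187 and 0.820). Higher as well were adipocyte (none of 7; 0.0248 and 0.815) and mural and fibroblast (none of 9; 0.0440 and 0.820). Lower was gluconeogenesis and insulin response (1 of 10; 0.0386 and 0.689). Among BMP receptors, ligands and SMADs 1 of 18 was higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.0797). No gene passed without the Rosa control male, the Rosa 16OHE male or the Rosa control female, and 1 passed without the R899X control male or the R899X 16OHE male. The count was 2 without the R899X control female or the Rosa 16OHE female, and 3 without the R899X 16OHE female.

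**Figure D3:**
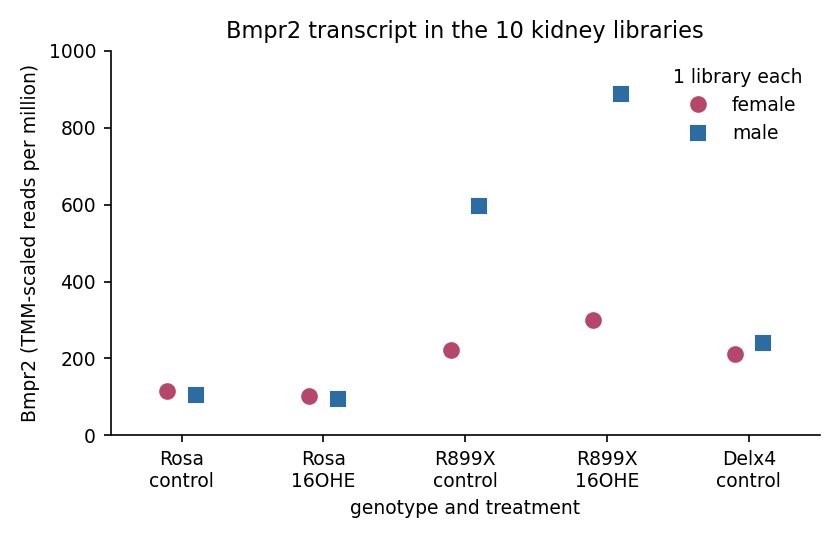
Bmpr2 transcript in TMM-scaled CPM for each genotype and treatment, with 1 point per library, circles for females and squares for males. The 4 Rosa libraries lie between 93.4 and 115, the 2 Delx4 libraries at 210.3 and 241 and the 4 R899X libraries between 223 and 888.

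Delx4 kidneys likewise held more Bmpr2 transcript than Rosa controls, at 210.3 and 241 CPM against 106 and 115 (n = 2 against 2), a difference of 1.16 ± 0.38 that did not pass (adjusted p = 0.499). Cwc22 rose by 2.32 ± 0.29, the hexosamine metabolism gene Gnpda1 by 1.03 ± 0.10 and Cth, whose product makes cysteine, by 1.00 ± 0.13. Lower in Delx4 were Angpt2, an angiopoietin gene (-1.42 ± 0.19), the secreted matrix protein gene Egfl6 (-1.30 ± 0.14), the lymphatic regulator gene Prox1 (-1.16 ± 0.17) and the transcription factor gene Foxc1 (-0.74 ± 0.09). The urea transporter gene Slc14a1 (-1.86 ± 0.19), the interferon-induced gene Ifit2 (-1.32 ± 0.16), the glycolytic gene Aldoc (-1.25 ± 0.17) and Fam43a (-1.05 ± 0.11) were lower as well.

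By edgeR's quasi-likelihood test, 14 genes passed for Delx4, 5 higher and 9 lower, with adjusted p from 0.00703 for Fam43a to 0.0468 for Prox1; DESeq2 called 118. Chosen after their values were seen, the other 3 were Gm5514 (-1.11 ± 0.11), Azgp1 and the steroid dehydrogenase gene Hsd3b5. Azgp1 had 870 reads over the Delx4 libraries, of which 851 were in the male, and 3 over the Rosa controls, a ratio of 216 with a 95% counting interval of 73.8 to 1051. Hsd3b5 had 247 reads, of which 196 were in the female, against 1, a ratio of 184 with an interval of 32.8 to 7306. Camera called 9 lists, none of them with an estimated correlation and none with a member past the test over all genes. Higher were immediate early (none of 10 adjusted over the list alone; camera, adjusted p = 6.27e-09; adjusted p = 0.624 with an estimated correlation), proximal tubule (none of 12; 0.00766 and 0.624) and erythroid (none of 4; 0.0162 and 0.624). Lower were interferon response (1 of 11; 0.000164 and 0.213), collecting duct principal cell (3 of 8; 0.000776 and 0.624) and mural and fibroblast (none of 9; 0.000776 and 0.642). So were thick ascending limb (1 of 6; 0.00459 and 0.624), extracellular matrix (none of 11; 0.00850 and 0.721) and macrophage and myeloid (none of 9; 0.0162 and 0.624). No gene passed without the Delx4 control male or the Rosa control female, 2 without the Rosa control male, 9 without the R899X 16OHE female and 30 without the Delx4 control female. The count was 101 when the 4 Rosa and Delx4 control libraries were fitted alone.

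Cwc22 and Azgp1 were called in both mutant genotypes, against 0.00514 genes if the calls were independent and none in any of 20 simulated data sets with the same shared Rosa libraries and no genotype effect. With no effect in any gene few calls remain to be shared, so that last count does not measure chance from shared libraries. Across genes, which are not independent replicates, the R899X and Delx4 differences had a correlation of 0.441, against a mean of 0.389 in those simulations, and a covariance of 0.0720 against 0.0366.

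The response to 16OHE was not shown to differ between R899X and Rosa for any gene. Col6a2 had the smallest p, with a response difference of -1.08 ± 0.17 (adjusted p = 1.00). The tight junction gene Cldn1 (-0.91 ± 0.16), the collagen cross-linking gene Lox (-2.29 ± 0.41), the matrix protein gene Sparc (-1.07 ± 0.19) and Dcn (-1.47 ± 0.27) had the next smallest p and did not pass. By edgeR's quasi-likelihood test 0 genes passed. Of all genes 535 had an unadjusted p under 0.05 where 817 would by chance. Such a shortfall marks a conservative test and is no evidence of equal responses. The fit held no term for 16OHE by sex. DESeq2 called 3 genes and limma-voom 0. Camera called lists of mesenchyme and early response lower in R899X. These were extracellular matrix (5 of 11 lower adjusted over the list alone; camera, adjusted p = 1.06e-15; adjusted p = 0.196 with an estimated correlation), adipocyte (4 of 7; 2.07e-15 and 0.196), mural and fibroblast (2 of 9; 9.65e-10 and 0.317) and immediate early (8 of 10; 1.21e-17 and 0.310). It also called tubular injury (none of 10; 3.59e-05 and 0.310), BMP target genes (1 of 11; 0.0125 and 0.310), podocyte (1 of 7; 0.0130 and 0.637) and B cell and plasma cell (none of 7; 0.0169 and 0.513) lower. It called male-biased genes (none of 15; 0.000808 and 0.649) and NRF2 targets (none of 10; 0.0205 and 0.628) higher. None of these 10 lists had a member past the test over all genes.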

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

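In this part, the test for female RNA in the male libraries was chosen only after the result was seen, as was the use of library pairs instead of fitted changes in the test of shared controls.

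A test of the difference between the sexes in the response to 16OHE, by the interaction term, singled out 393 genes. The largest excesses of the male over the female log2 change were 5.68 for Slc7a12, 4.74 for Nptx1, 4.21 for Slc17a2, 4.07 for Fabp1 and 4.05 for Ugt1a2. The largest deficits were -6.14 for Cyp7b1, -4.44 for Inmt, -4.44 for Itih2, -4.39 for Rtp3 and -4.30 for Cyp2j13.

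Over sex-biased genes as a set, with exceptions such as Kap, 16OHE in males was accompanied by a shift toward the level in females. Of 887 genes that differed in the Delx4 pair by more than 1 on the log2 scale, 347 were higher in the male, of which 79.8% were lower with 16OHE in the Rosa and R899X males (median -0.59), and 540 higher in the female, of which 73.1% were higher (median 0.34), against 40.9% and 56.5% in females. Control libraries shared by both comparisons are argued against as the whole cause by the slope of the change in these 4 male libraries on the Delx4 difference, which shares no library with it. The slope was -0.28 (95% interval -0.32 to -0.25 over 1000 resamples of chromosomes). In females it was 0.05 (0.02 to 0.09). These intervals hold the libraries fixed and cover the spread over genes, not that between pools. Female RNA in the male libraries is argued against by Xist, which reached 1.02 CPM at most in the 16OHE males. That lay within the 0.93 to 2.41 of the control males and far from the lowest female at 416. A smaller share of proximal tubule cells is argued against as the whole cause by that list's median of -0.33 (SD 0.63), against -1.52 for the male-biased list. As part of the cause it stays open, since camera at the preset correlation called that list lower in males. Whether all segments of the tubule changed alike was not tested. Also open are an estrogenic effect of 16OHE in males, which these values do not contradict, and copper. Under the reading by library number both 16OHE male libraries and no male control were supplemented, so the treatments cannot be told apart in males.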

How the results depend on the processing

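No alternative in this part was chosen after the result was seen. For 360 pairs of a named gene and a comparison, 6767 alternative values were computed: 5811 kept the call and its direction, 949 lost the call, 7 gained it and none reversed. Losses were uneven over the alternatives: with the copper term by library number, 191 of the 360 pairs kept the call and 169 lost it. Where a number below differs, the cause was not tested unless stated. Counts for sex, 16OHE and both contrasts within a sex stayed within 1.5-fold under limma-voom, DESeq2 size factors, the higher minimum count and counts without strand. DESeq2 called 1505 genes for 16OHE, 34 for R899X, 118 for Delx4 and 3 for 16OHE by R899X. Limma-voom called 2 for R899X. With no filter on low counts there were 26 for R899X, 87 for Delx4, 981 for 16OHE by sex, 2 for 16OHE by R899X and 994 for 16OHE in females. With the copper term by library number there were 2034 for sex, 13 for 16OHE, 2 for R899X, 83 for 16OHE in females and 428 in males; under that reading the term parts 16OHE from control in all but 1 library, which by construction leaves little to estimate the treatment from. With the term by list position there were 1 for R899X and 8 for Delx4. The model of conditions gave 2 for R899X and 7 for Delx4, and the 4 Rosa and Delx4 control libraries alone 101 for Delx4.

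Leaving out each library in turn gave 1950 to 3114 genes for sex, 396 to 1050 for 16OHE, 0 to 8 for R899X, 0 to 30 for Delx4, 113 to 573 for 16OHE by sex, 0 to 0 for 16OHE by R899X, 103 to 490 for 16OHE in females and 679 to 2100 in males; where this left a level with 1 library, that library is assumed to vary like the others. With an estimated correlation camera called 1 list for sex, against 13 with the preset one, and 0 for 16OHE, R899X, Delx4, 16OHE by sex and 16OHE by R899X, against 12, 6, 9, 9 and 10. Fry called 18 for sex, 4 for 16OHE and 0 for each of the other 4. Depth limits genes of low abundance: in simulated data over the 6 comparisons, 2-fold changes were recovered for 36.8% of changed genes below the median level and 89.7% above it.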

Other observations

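In this part, the test of copper by library number, the test of neighbouring genes and the simulated share of equal signs were chosen only after the result was seen. So were the use of the simulated count of genes called in both genotypes and the choice of collagen VI as the genes that marker lists are set against. The other tests were chosen beforehand.

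In males, camera called neither the iron handling list (3 of 9 higher and 2 lower, adjusted p = 0.844), the circadian clock (1 of 14 higher and 3 lower, 0.252), BMP receptors, ligands and SMADs (2 of 18 higher and 1 lower, 0.918), BMP targets (1 of 11 higher and 2 lower, 0.844) nor the thick ascending limb (2 of 6 higher, 0.0861) with 16OHE (n = 2 against 2). Members that passed on their own included the iron exporter gene Slc40a1 (0.94 ± 0.09), the clock gene Cry1 (1.15 ± 0.23), the BMP antagonist gene Grem1 (1.35 ± 0.20) and Umod, which encodes uromodulin (0.65 ± 0.13), all higher, and the BMP target gene Id3, which fell by 0.88.

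Collagen VI and other matrix genes were higher with 16OHE, with a median of 2.74 over 6 collagen VI genes. More fibroblasts or mural cells cannot be told apart from a change within cells. The median of their markers was 0.61 (range -0.51 to 1.74, SD 0.89), below that of collagen VI. But the marker list itself holds matrix genes, and its upper end is Col1a1 at 1.74. It therefore cannot separate cell number from the level of matrix genes. Of the collagen VI genes, Col6a5 and Col6a6 were at -0.01 and -0.18. Adipose tissue is argued against by an adipocyte median of -0.11 (range -3.32 to 0.39). Copper by library number cannot be told apart from 16OHE, since 1 supplemented control excludes nothing: in the R899X control female the collagen VI median was 0.51 above the other control females, and over the 274 genes called in both sexes its difference had the sign of the Rosa male change in 69.3%, with a median of 0.15 in that direction against a size of 1.36, and a slope of 0.04. These values may thus be due to 16OHE, to copper or to both, with or without a change in cell numbers.

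Cwc22 and Azgp1 were higher than Rosa in both mutant genotypes. Cwc22 was higher by 1.47 to 2.53 in 4 pairs of libraries that share none between the genotypes, while Azgp1 had too few reads in Rosa for such values, but both were picked for being called in both genotypes from these same libraries. Over the 18 genes called in either genotype such pairs had the same sign in 14 (77.8%), against 86.0% on average and 75 to 100% in 20 simulated data sets with no genotype effect and genes picked alike. Selection alone gives such a share, so it cannot tell chance values of the shared Rosa libraries from a common effect. As for the 2 genes called in both genotypes, 0 genes were called in both in those 20 data sets. This count cannot decide on such chance values either. With no genotype effect in any gene, the adjustment leaves few calls to be shared. The data sets also gave genes of the same level the same spread. Cwc22 was at 38.9 to 88.4 CPM in the mutant libraries and 13.1 to 16.4 in the Rosa libraries, 16OHE ones included. Linked segments from another strain stay open as a source of small p-values for R899X, which they are consistent with: the 35 genes with p under 0.001 formed 29 pairs within 10 megabases, against 5.94 on average and 17 at most in 1000 random draws of tested genes (permutation p = 0.001, the smallest these draws can give), while a test by whole chromosome (smallest adjusted p = 0.128, for chromosome 11 with 8 genes against 2.85 expected), set beforehand to decide this, can miss short segments and decides nothing. An effect of the Bmpr2 mutations stays open as well, untested.

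For sex, 1 of 100 splits drawn from 126 gave as many genes, the real one, with 3150 against 1 at most in the others. For 16OHE, 1 of 34 splits did, the real one, with 947 against 2 at most in the others. For 16OHE, 1 further split could not be fitted. Both shares lie below the limit set beforehand, but the rank of the real split does not decide against chance. Libraries were split freely over sex, genotype and treatment and are not interchangeable, while the real splits are balanced over the other factors. The size of the gap does not measure chance. The other splits were fitted without the real factor, whose effect then entered their residual spread. For R899X, 2 of 34 splits gave at least the 6 genes of the real one, so chance cannot be excluded by the share set beforehand. The other of these splits called 30 genes and set control males with 16OHE females against the rest. That is the contrast of sex by treatment, so it points to a structure of the samples, and no further split called more than 2 genes.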
